A study of Mus musculus with 13 samples.

How the data were processed

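RNA-seq was analysed from 10 bulk libraries of mouse hematopoietic stem and progenitor cells (HSPCs) from bone marrow, in the 4 groups that the labels name: wild type (n = 2), Setd2 knockout (n = 2), Srsf2 mutated (n = 3) and Setd2 knockout with Srsf2 mutated (n = 3), called double mutant here. The 3 single-cell samples of the series were not analysed here. For those single-cell samples the labels describe lineage-negative c-Kit-positive cells of mice carrying Mx1-Cre, a recombinase switched on by pIpC, taken 4 weeks after induction in a bone marrow transplant model. The sort, the transplant and the time are not stated for the bulk libraries, and the labels do not say whether replicates of a group came from separate mice. Neither the strain nor the sex of the mice nor the strandedness of the libraries is given in the sources used here. Per the labels, the libraries were sequenced on an Illumina NovaSeq instrument.

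The data were 3 deposited tables, each holding a pair of groups. Per the file headers, each table gives a whole-number read count per gene and library, and these counts were the values used. Per the file headers, the tables also give FPKM, which equalled the count divided by the listed gene length and by the library's total count. The authors' log2 fold change with its standard error, and the authors' p-value and adjusted p-value, stand in the same deposited tables. The deposited column of mean normalised counts (a score of abundance from the authors' fit) was read only to see which libraries that fit held. The authors' processing notes list HISAT2 2.0.5, SAMtools 1.7, HTSeq 0.9.1, STAR 2.6.1a, featureCounts 2.0.1, DESeq2 1.22.2 and Seurat 3.2.0, with mouse and human genome builds, without saying which step used which. The 5 libraries that stand in 2 tables had identical counts in both, so the tables were joined on the Ensembl identifier over 55421 genes. All columns of single samples were assigned to a library (0 left over). A total of 27 gene symbols had been turned into dates and were restored from the identifiers. Positions were taken from GENCODE M21 on GRCm38, which held 99.89% of the tested genes.

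Genes with too few counts were removed by filterByExpr of edgeR 4.0.16 (R 4.3.3), which left 19289 tested genes. Counts were scaled by TMM factors, and 1 quasi-likelihood model was fitted over all 10 libraries with a term per group. Of it 4 contrasts were tested: Setd2 knockout against wild type, Srsf2 mutated against wild type, double mutant against Srsf2 mutated, and the difference between the first and the third of these, which is the interaction. Each p was adjusted by the Benjamini-Hochberg method over all tested genes, and a gene was called changed at an adjusted p under 0.05 in either direction. Expression is given as CPM, each library's counts scaled by its TMM-adjusted total, with the SD over libraries, and fold changes carry the SE of the fit on the log2 scale. For a group with 0 counts in each library, a fold is given as a lower bound against 3 counts summed over the group, which is 0.0353 CPM in wild type, 0.0321 in Setd2 knockout, 0.0225 in Srsf2 mutated and 0.024 in double mutant. These floors cover counting error only, since reads without molecular identifiers are not independent molecules.

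Gene groups were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the 30 lists of each comparison; each list had at least 5 tested members. The lists covered hematopoietic stem cells, early neutrophils, late neutrophils, myeloid-derived suppressor cells, erythroid cells, megakaryocytes, B lymphoid cells, T and NK cells, mast cells and basophils, eosinophils, monocytes and macrophages, dendritic cells, and endothelial and stromal cells. Others covered NF-kB and TNF targets, interferon-stimulated genes, Toll-like receptor and interleukin-1 signaling, cytokine receptors with JAK-STAT, mitosis, DNA replication, p53 targets, splicing factors, chromatin methyltransferases and demethylases, splicing targets and kinases tied to the study's subject, immediate early and heat shock genes, the unfolded protein response, ribosomal proteins, oxidative phosphorylation, mitochondrially encoded genes, replication-dependent histones, and sex-linked genes. Beside each test stand the members called over all tested genes and those called when p was adjusted over the list alone. The lists, the tests, the alternative settings and the rule for naming genes were set before the data were examined.

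Genes were named by that rule: Setd2, Srsf2, Mki67, S100a8, S100a9, Mpo, Arg1, Nos2 and Il1b everywhere (9 genes), and per comparison the 8 genes with the largest fold change in each direction. Those had to reach a mean of 4 CPM in the higher group with no overlap of the groups' library values, and predicted models and immunoglobulin segments were left out. The rule adds the 3 members of smallest adjusted p from each list that was called or had at least 3 changed members, up to 2 from other lists, and for the interaction the 5 genes of smallest adjusted p in each direction. Genes named outside it are said to have been chosen after their values were seen.

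The alternatives were median-of-ratios or upper-quartile scaling, no filter, a filter of 5 CPM in 2 libraries, a replicate block, a fit with only the 2 groups compared, DESeq2 1.42.0, leaving out each library in turn, and camera with a correlation estimated per list. A minimum change of 2-fold and the removal of genes on X and Y were added after seeing the data. Alternatives planned for tables without counts did not apply. The pipeline was tested on simulated data with known changes: of genes changed 2-fold, 89.6% were recovered in Setd2 knockout against wild type, 83.6% in Srsf2 mutated against wild type, 83.6% in double mutant against Srsf2 mutated and 70.1% in the interaction. Of genes left unchanged, it called 3 of 18257, 8 of 18222, 17 of 18297 and 6 of 18269. Beside the list raised on purpose, camera called 0, 1, 0 and 2 others of the 30. The simulation changed few genes, single ones evenly in both directions, and gave a gene the same dispersion in all groups. Far more genes were called in the real data, so these rates need not hold there. Copies of Rpl29 in the genome were searched with blastn 2.17.0 at 85% identity over at least 200 bases, and plots were drawn with Python 3.11.15 and matplotlib 3.10.9.

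The deposited comparisons hold 7419 genes at an adjusted p under 0.05 for Setd2 knockout against wild type, 10833 for Srsf2 mutated against wild type and 1476 for double mutant against Srsf2 mutated. Across genes, their log2 fold changes correlated with those of the edgeR fit at r = 0.996, 0.998 and 0.994, with genes not being independent replicates. In the deposited double mutant table the mean normalised count of Mpo is 1467640, above its highest count of 506880 in any of the 10 libraries, so that fit appears to have included libraries that were not used here.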

Results

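Bulk RNA-seq of mouse HSPCs was compared between 4 genotypes formed by the loss of Setd2, a histone methyltransferase of transcribed genes, and a mutation of Srsf2, a splicing factor. The series title ties both genes to myeloid-derived suppressor cells and inflammatory signaling in myelodysplastic syndrome. Total counts were 45176730 and 45499806 in the wild type libraries, and 42367739 and 43507677 in the Setd2 knockout libraries. They were 42941336, 47341114 and 39142427 in the Srsf2 mutated libraries, and 32117387, 47574119 and 50445434 in the double mutant libraries. The first principal component (52.8% of the variance) ordered the libraries from wild type (-130.2 and -123.2) through Setd2 knockout (-66.1 and -68.1) and Srsf2 mutated (29.3 to 46.3) to double mutant (89.2 to 89.6). On the second (15.7%), Srsf2 mutated replicate 3 (75.5) stood apart from the other Srsf2 mutated libraries (36.9 and 42.5). Variation between libraries of a group, as a coefficient, was 0.104 in wild type, 0.0563 in Setd2 knockout, 0.192 in Srsf2 mutated and 0.0782 in double mutant. The labels do not say whether these libraries came from separate mice, so this spread may not be that between mice. The p-values below rest on it and carry the same limit.

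Setd2 (ENSMUSG00000044791, chromosome 9, 110532597 to 110618633 on GRCm38) stood at 151.7 ± 9.63 CPM (SD, n = 2) in wild type and 221.7 ± 12.9 (n = 2) in Setd2 knockout. It stood at 197.1 ± 34.8 (n = 3) in Srsf2 mutated and 130.4 ± 0.87 (n = 3) in double mutant libraries. By the edgeR quasi-likelihood test it was higher in the libraries labelled Setd2 knockout than in wild type (log2 fold change 0.55 ± 0.121 SE, adjusted p = 0.00204) and lower in double mutant than in Srsf2 mutated libraries (-0.60 ± 0.0988, adjusted p = 0.000182). Between Srsf2 mutated and wild type it differed by 0.38 ± 0.111 (adjusted p = 0.00879, and 0.0908 without wild type replicate 2). Srsf2 (ENSMUSG00000034120, chromosome 11, 116849901 to 116853094) stood at 263.4 ± 26.7, 323.4 ± 2.22, 231.2 ± 12 and 223.4 ± 4.03 CPM in the same order of groups. Its difference was 0.30 between Setd2 knockout and wild type (adjusted p = 0.00856, and 0.104 without wild type replicate 2) and -0.19 between Srsf2 mutated and wild type (adjusted p = 0.0391). The latter call ended with median-of-ratios (adjusted p = 0.0739) or upper-quartile scaling (-0.09, 0.319), the stricter filter (-0.05, 0.548), only the 2 groups compared (0.18) and DESeq2 (0.0601). It also ended without wild type replicate 1 (-0.09, 0.403), Srsf2 mutated replicate 1 (0.118) or Srsf2 mutated replicate 2 (0.0954). A count over a whole gene need not show the deletion of some of its exons and cannot show a point mutation, so these levels check neither genotype. Xist, the RNA that silences 1 X chromosome in female cells, stood at 485.5 ± 19.7 CPM in wild type, 0.5982 ± 0.0517 in Setd2 knockout, 1.783 ± 0.655 in Srsf2 mutated and 7.405 ± 0.565 in double mutant libraries. Ddx3y, a gene of the Y chromosome, had 0 counts in the wild type and Setd2 knockout libraries, and 111.2 ± 7.91 and 123.6 ± 4.39 CPM in the Srsf2 mutated and double mutant libraries. The sex-linked state of the libraries therefore changed together with genotype in both comparisons with wild type. The interaction contains 1 of these comparisons, so it carries that difference too.

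**Figure D1:**
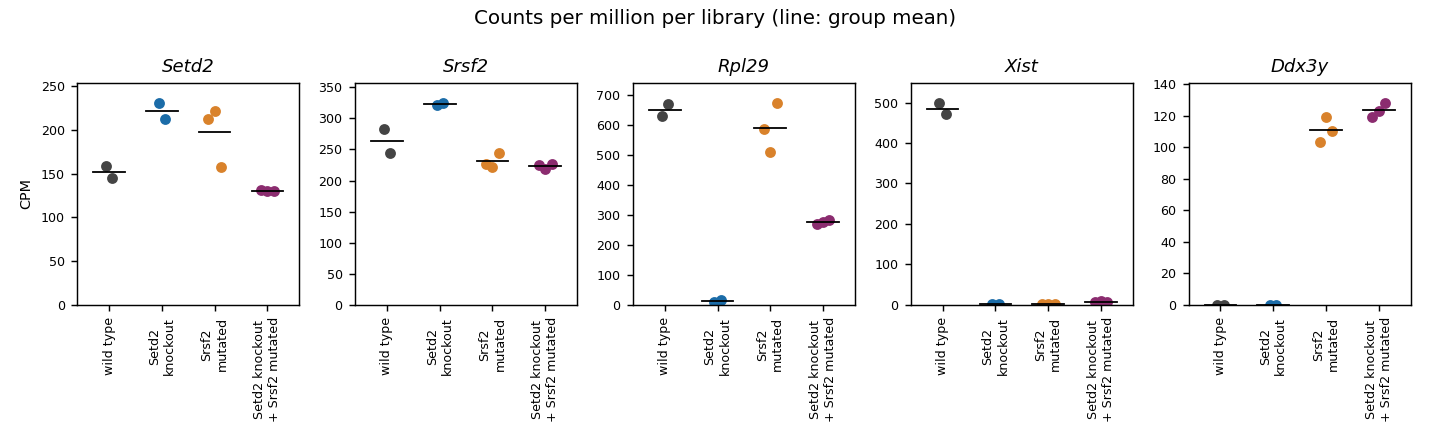
CPM of Setd2, Srsf2, Rpl29, Xist and Ddx3y in each of the 10 libraries by group (points are libraries, lines the group mean, linear axes from 0). Xist lies at 471.5 and 499.4 CPM in the wild type libraries and under 8 CPM in the others, and Ddx3y is at 0 in wild type and Setd2 knockout libraries.

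Setd2 knockout against wild type (n = 2 and 2) asks what the loss of Setd2 did with normal Srsf2. Genes of red cell formation were higher, and genes of neutrophils, suppressor cells and eosinophils lower, in the knockout libraries. Rhag (ENSMUSG00000023926, chromosome 17, 40811126 to 40840754), a membrane protein of red cell precursors, went from 14.95 ± 0.484 to 86.76 ± 5.66 CPM, 5.8-fold higher (log2 fold change 2.54 ± 0.1 SE, adjusted p = 1.24e-10 by the edgeR quasi-likelihood test with the Benjamini-Hochberg method). S100a8 (ENSMUSG00000056054, chromosome 3, 90668978 to 90670035), a calcium-binding protein abundant in neutrophils, went from 3979 ± 551 to 1189 ± 75.2 CPM (-1.74 ± 0.132, adjusted p = 8.26e-08). Prg2 (ENSMUSG00000027073, chromosome 2, 84980461 to 84983632), the major basic protein of eosinophil granules, went from 459.8 ± 6.93 to 81.89 ± 7.38 CPM, which is 5.61-fold lower (-2.49 ± 0.0973, adjusted p = 1.18e-10).

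Of 30 tested erythroid genes, 28 rose and 0 fell (28 and 0 adjusted over the list alone), with a median log2 fold change of 1.58 and a camera adjusted p = 1.09e-60. Among them Kel, a blood group protein, rose 10.2-fold (3.34 ± 0.134) and Car2, a carbonic anhydrase, rose 3.5-fold (1.81 ± 0.0795). Globin transcripts made up 0.022% and 0.0215% of counts in the knockout libraries against 0.00847% and 0.00829% in wild type. All 18 early neutrophil genes fell (18 adjusted over the list alone; median -0.94, adjusted p = 2.59e-20), among them the protease gene Prss57 at -1.02 ± 0.0736. Mpo, the peroxidase of primary granules, went from 11910 ± 18.3 to 6927 ± 415 CPM (-0.78 ± 0.0742, adjusted p = 8.41e-07). Of 23 late neutrophil genes, 21 fell and 0 rose (the same adjusted over the list alone; median -1.48, adjusted p = 9.31e-26), including Ltb4r1, a leukotriene receptor, at -1.59 ± 0.0956, and Itgb2l, an integrin, at -1.81 ± 0.119. Of 31 suppressor cell genes, 20 fell and 2 rose (21 and 3 adjusted over the list alone; median -0.65, adjusted p = 3.32e-12). Trem1, an activating receptor of myeloid cells, fell among them from 43.03 ± 0.687 to 15.02 ± 0.127 CPM. Of 10 eosinophil genes, 8 fell and 0 rose (the same adjusted over the list alone; median -2.37, adjusted p = 2.45e-23), with Epx, the eosinophil peroxidase, at -2.46 ± 0.116.

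Of 46 splicing factor genes, 23 rose and 6 fell (23 and 8 adjusted over the list alone; median 0.25, adjusted p = 0.000168). The kinases Clk4 and Clk1, which phosphorylate splicing factors, rose by 1.48 ± 0.084 and 1.38 ± 0.0977, and Srsf5, a relative of Srsf2, rose by 1.13 ± 0.0724. Ribosomal protein genes (4 higher and 53 lower of 87, 5 and 65 adjusted over the list alone, median -0.35, adjusted p = 4.98e-07) and oxidative phosphorylation genes (2 and 53 of 78, 2 and 57 adjusted over the list alone, -0.40, adjusted p = 3.4e-07) were called lower. With an estimated correlation these gave adjusted p = 0.562 and adjusted p = 0.56. Further lists called lower only with the preset correlation were megakaryocyte genes (12 of 22 lower, 0 higher; adjusted p = 0.112 with an estimated correlation) and the unfolded protein response (15 of 28 lower, 3 higher; adjusted p = 0.476). The same holds for replication-dependent histones (14 of 53 lower, 2 higher; adjusted p = 0.467), Toll-like receptor and interleukin-1 signaling (17 of 35 lower, 4 higher; adjusted p = 0.507) and cytokine receptors with JAK-STAT (16 of 32 lower, 3 higher; adjusted p = 0.476). The counts of these lists were the same adjusted over the list alone, apart from 18 lower in the unfolded protein response. The Toll-like receptor and cytokine receptor calls also ended without wild type replicate 1 (adjusted p = 0.101 and 0.0609) and without Setd2 knockout replicate 2 (0.0559 and 0.0652). The erythropoietin receptor gene Epor, a member of the cytokine receptor list, rose 4.17-fold.

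Several of the largest changes lay within 20 Mb of Setd2 on chromosome 9. Mst1r (ENSMUSG00000032584, 107906873 to 107920383), a receptor tyrosine kinase, went from 0.7292 ± 0.0999 to 38.41 ± 0.761 CPM, 52.5-fold higher. The chemokine receptor genes Ccr1 (123962124 to 123968692) and Ccr2 (124101950 to 124113557) rose 10.7-fold (3.41 ± 0.0947) and 6.16-fold (2.62 ± 0.0798). Rpl29 (ENSMUSG00000048758, 106429454 to 106431568), a ribosomal protein gene, went from 649.7 ± 27.5 to 12.36 ± 3.17 CPM (-5.71 ± 0.163, adjusted p = 2.51e-12). Il1b, the gene of interleukin-1 beta, stood at 1.905 ± 0.366 and 2.104 ± 0.226 CPM (0.14 ± 0.158, adjusted p = 0.505). Mki67, expressed in dividing cells, stood at 731.1 ± 4.55 and 833.8 ± 37.4 CPM (0.19 ± 0.122, adjusted p = 0.239, and 0.0369 with only the 2 groups compared). Arg1, an arginine-consuming enzyme of suppressor cells, stood at 0.1294 ± 0.0499 and 0.5354 ± 0.129 CPM. Its adjusted p = 0.0307 became 0.0628 without wild type replicate 1, 0.171 without wild type replicate 2 and 0.148 without Setd2 knockout replicate 1. Nos2, another such enzyme, had 0 counts in wild type and 0.04276 ± 0.000628 CPM in the knockout libraries (adjusted p = 0.0812).

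In all, 7449 of 19289 genes changed, 3603 higher and 3846 lower (1984 and 542 at a change of at least 2-fold). Without Setd2 knockout replicate 1 these were 2392 and 2400, which is 4792 in all. With upper-quartile scaling 59.5% of the called genes were higher (4275 and 2911), against 48.4% here, so the split by direction is not fixed by the data. Of the 30 lists 14 were called, and 7 of them with an estimated correlation as well: erythroid, early and late neutrophil, suppressor cell, eosinophil, splicing factor and sex-linked. Camera adjusted p with that correlation was 0.0447 for early neutrophil, late neutrophil and splicing factor genes, and 0.000251 for erythroid genes. In the sex-linked list 1 of 5 genes was lower, which is Xist (median 0, mean -1.93, adjusted p = 8.99e-07). The lists not called included interferon-stimulated genes (8 of 41 higher, 6 lower, and 7 and 6 adjusted over the list alone) and mast cell and basophil genes (7 of 18 higher, 4 lower). Mitochondrially encoded genes (6 of 15 higher, 0 lower, camera adjusted p = 0.109) were called higher with a replicate block (adjusted p = 0.0184). They were also called higher without wild type replicate 1 or Setd2 knockout replicate 2. NF-kB and TNF target genes (4 of 33 higher, 11 lower) were called lower without wild type replicate 2 (adjusted p = 0.0317), and B lymphoid genes (2 of 23 higher, 10 lower) without wild type replicate 1 (adjusted p = 0.0175). Immediate early and heat shock genes (7 of 29 higher, 9 lower, median -0.19, mean 0.01, adjusted p = 0.905) were called higher without wild type replicate 1 (adjusted p = 0.0281) and lower without wild type replicate 2 (adjusted p = 0.000168).

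Srsf2 mutated against wild type (n = 3 and 2) compares libraries with and without the Srsf2 mutation at normal Setd2. The sex-linked state differs between these groups too, and the sort of the bulk cells is not stated. In this comparison, as in the others, a difference in the cells collected cannot be told apart from an effect of the genotype. NF-kB and TNF target genes, immediate early and heat shock genes, and genes of B cells, mast cells and red cells were higher in the mutated libraries, and early neutrophil genes were lower. Il6 (ENSMUSG00000025746, chromosome 5, 30013114 to 30019981), the gene of the cytokine interleukin-6, went from 0.2235 ± 0.116 to 102.3 ± 10.6 CPM (log2 fold change 8.82 ± 0.19 SE, adjusted p = 8.53e-15 by the edgeR quasi-likelihood test). Il1b (ENSMUSG00000027398, chromosome 2, 129364570 to 129371139) went from 1.905 ± 0.366 to 49.04 ± 3.4 CPM, 25.7-fold higher (4.68 ± 0.123, adjusted p = 7.21e-14). Blnk (ENSMUSG00000061132, chromosome 19, 40928927 to 40994535), an adaptor of the B cell receptor, rose 11.4-fold (3.51 ± 0.0955), and Mpo (ENSMUSG00000009350, chromosome 11, 87793581 to 87804413) fell to 4293 ± 295 CPM (-1.47 ± 0.0665, adjusted p = 4.4e-11).

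Of 33 NF-kB and TNF targets, 26 rose and 3 fell (the same adjusted over the list alone; median 2.26, adjusted p = 1.42e-28), including Irf1, an interferon response factor, from 42.48 ± 0.361 to 249.6 ± 14.5 CPM. Of 29 immediate early and heat shock genes, 24 rose and 2 fell (the same adjusted over the list alone; median 2.22, adjusted p = 1.58e-29). The chaperone genes Hspa1b and Hspa1a rose 36.4-fold and 58.9-fold, and Egr3, an early transcription factor, rose 77-fold. Nlrp3, the sensor of an inflammasome, went from 4.563 ± 0.133 to 229.7 ± 23 CPM, and Socs3, a feedback inhibitor of cytokine signaling, from 6.869 ± 0.966 to 532.2 ± 22.8 CPM. The lists that hold these genes were not called, with 11 of 35 Toll-like receptor and interleukin-1 genes higher and 15 lower (adjusted p = 0.312), and 8 of 32 cytokine receptor genes higher and 16 lower (adjusted p = 0.16). In both the median was below 0 and the mean and the test above it. Interferon-stimulated genes were not called either (14 of 41 higher, 17 lower; 14 and 18 adjusted over the list alone; adjusted p = 0.948, median -0.22, mean 0.07), though Rsad2, an antiviral enzyme, rose 8.22-fold.

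All 23 tested B lymphoid genes rose (23 adjusted over the list alone; median 3.03, adjusted p = 4.13e-41), among them Igll1, part of the surrogate light chain, 11.3-fold, and the coactivator Pou2af1 8.46-fold. Of 18 mast cell and basophil genes, 12 rose and 0 fell (the same adjusted over the list alone; median 2.06, adjusted p = 6.13e-15), with the steroid enzyme gene Cyp11a1 16-fold higher. Of 24 T and NK genes, 18 rose and 0 fell (the same adjusted over the list alone; median 1.51, adjusted p = 0.0011), with Gzmb, the gene of granzyme B, 7.5-fold higher. Of 30 erythroid genes, 20 rose and 7 fell (21 and 7 adjusted over the list alone; median 0.65, adjusted p = 3.91e-23). Slc4a1 (ENSMUSG00000006574), the anion exchanger of red cells, went from 1.423 ± 0.482 to 308.8 ± 21.9 CPM, and Alas2, the first enzyme of erythroid heme synthesis, rose 126-fold. Globin transcripts made up 0.598%, 0.534% and 0.689% of counts in the mutated libraries.

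All 18 early neutrophil genes fell (18 adjusted over the list alone; median -1.34, adjusted p = 4.92e-22), among them Gfi1, a transcription factor of granulocytes, from 210 ± 6.3 to 49.34 ± 2.12 CPM. Late neutrophil genes went both ways, 9 of 23 higher and 8 lower (10 and 9 adjusted over the list alone; adjusted p = 0.16), and were called higher without wild type replicate 2 (adjusted p = 0.0123). The collagenase gene Mmp8 rose 6.28-fold (2.65 ± 0.0785), while S100a8 fell by 0.65 on the log2 scale (SE 0.116, adjusted p = 0.000199). S100a9 differed by -0.43 ± 0.122 (adjusted p = 0.00672, and 0.164 without wild type replicate 2 or 0.0703 with the stricter filter). Suppressor cell genes were called higher (15 of 31 higher, 9 lower, the same adjusted over the list alone; median 0.27, adjusted p = 0.00311; adjusted p = 0.0616 with an estimated correlation). In this list Ptgs2, the inducible cyclooxygenase, rose 17-fold. Arg1 stood at 0.6752 ± 0.316 CPM (adjusted p = 0.00604, and 0.0621 without wild type replicate 2), and Nos2 at 0.3778 ± 0.128 CPM was at least 10.7-fold higher. Hematopoietic stem cell genes were called lower (4 of 23 higher, 10 lower; 4 and 11 adjusted over the list alone; adjusted p = 0.132 with an estimated correlation and 0.0582 without Srsf2 mutated replicate 3), with the transcription factor gene Hlf 3.97-fold lower and Kit 2.05-fold lower.

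Mitosis genes (2 of 32 higher, 23 lower; adjusted p = 0.113 with an estimated correlation) and DNA replication genes (5 of 43 higher, 27 lower; adjusted p = 0.166) were called lower, with the mitotic kinase gene Plk1 2.43-fold lower. Mki67 stood at 878.2 ± 166 CPM against 731.1 ± 4.55 in wild type (0.26 ± 0.112, adjusted p = 0.0561), and passed the threshold with median-of-ratios (adjusted p = 0.0375) or upper-quartile scaling (0.0126), no filter (0.00258), the stricter filter (0.0111), a replicate block (0.0163) and DESeq2 (0.0233), and without Srsf2 mutated replicate 3 (0.41, adjusted p = 6.57e-06). Splicing factor genes (24 of 46 higher, 10 lower; adjusted p = 0.0836 with an estimated correlation) and p53 targets (14 of 29 higher, 7 lower; adjusted p = 0.0901) were called higher. Among these Srsf5 rose 4.26-fold and Cdkn1a, a cell cycle inhibitor, 7.14-fold. Eosinophil genes (7 of 10 higher, 2 lower; adjusted p = 0.31) and monocyte and macrophage genes (13 of 28 higher, 5 lower; adjusted p = 0.232) were called higher with the preset correlation. So were mitochondrially encoded genes (11 of 15 higher, 0 lower; adjusted p = 0.644), a call lost without wild type replicate 2 (adjusted p = 0.131) or Srsf2 mutated replicate 3 (0.0582). Ribosomal protein genes were called lower (5 of 87 higher, 59 lower; adjusted p = 0.709). The eosinophil, monocyte, mitochondrial and ribosomal values are those with an estimated correlation. Lists not called were dendritic cell (13 of 22 higher, 3 lower), endothelial and stromal (8 of 18 higher, 3 lower), megakaryocyte (3 of 22 higher, 12 lower), chromatin enzymes (9 of 44 higher, 16 lower), the study-related list (5 of 16 higher, 6 lower), unfolded protein response (10 of 28 higher, 12 lower), oxidative phosphorylation (6 of 78 higher, 28 lower) and histones (10 of 53 higher, 10 lower). Oxidative phosphorylation genes were called lower without wild type replicate 1 (adjusted p = 0.025) and without Srsf2 mutated replicate 3 (0.0063). The counts adjusted over the list alone differed in this paragraph for mitosis (3 and 23), p53 targets (15 and 7), dendritic cells (14 and 3), megakaryocytes (4 and 12), oxidative phosphorylation (5 and 28) and histones (10 and 8).

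In all, 10869 genes changed in this comparison, 5498 higher and 5371 lower (6160 and 4440 with upper-quartile scaling, 3633 and 1166 at a change of at least 2-fold). Of the lists 18 were called, and 8 of them with an estimated correlation as well: NF-kB, immediate early, B lymphoid, mast cell, erythroid, T and NK, early neutrophil and sex-linked. Camera adjusted p with that correlation was 0.000612 for NF-kB, 0.0246 for immediate early and 0.0293 for early neutrophil genes. The sex-linked list had 4 of 5 genes higher, all of the Y chromosome and at 0 in wild type, and Xist lower. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were at least 3150-fold, 1620-fold, 759-fold and 341-fold higher.

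**Figure D2:**
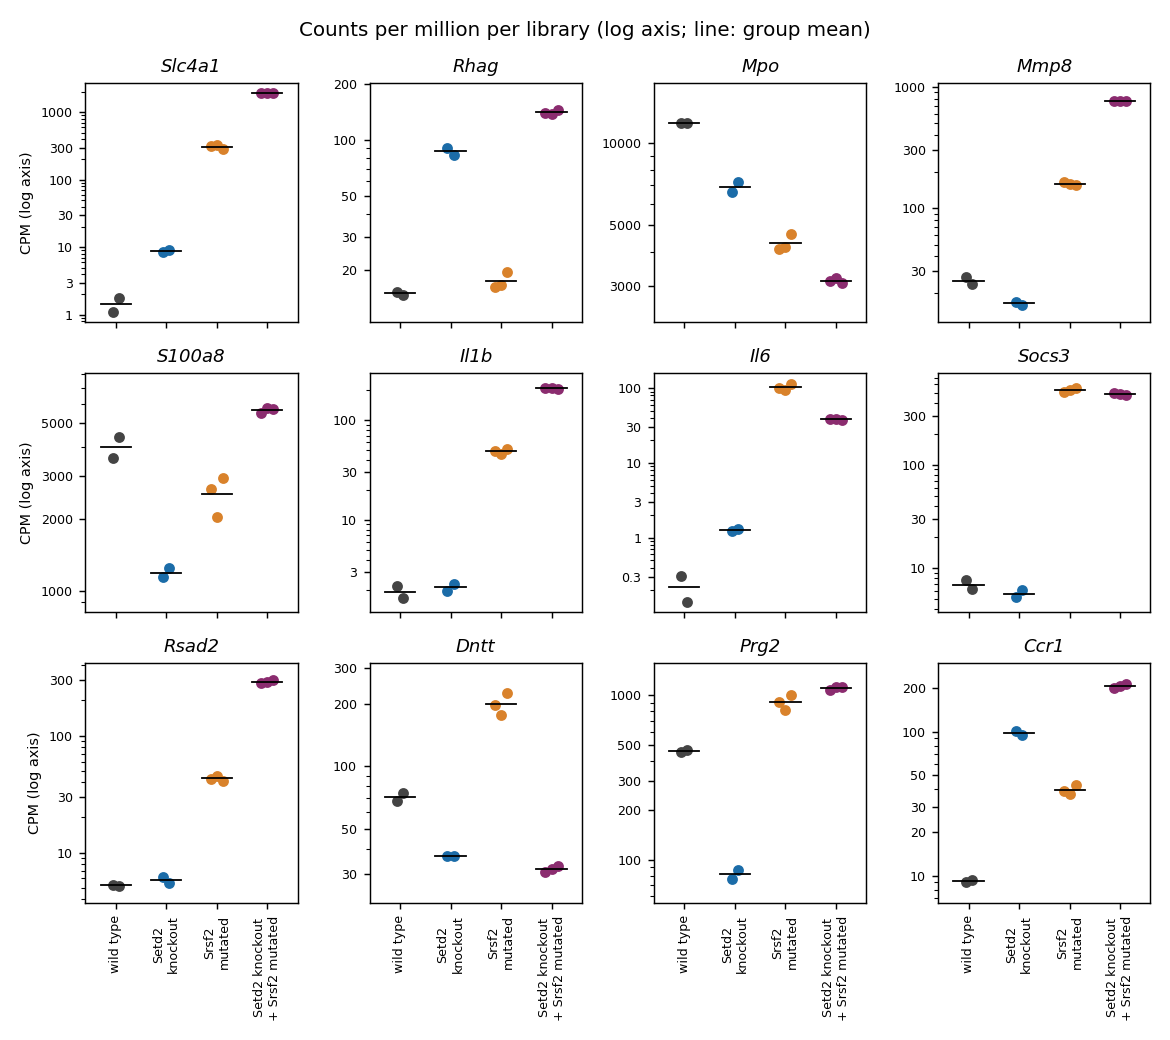
CPM of 12 genes in each library by group on log axes (points are libraries, lines the group mean). Il6 is highest in the Srsf2 mutated libraries at 102.3 CPM on average, while Slc4a1, Mmp8, Il1b and Rsad2 are highest in the double mutant libraries.

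Double mutant against Srsf2 mutated (n = 3 and 3) asks what the loss of Setd2 did in cells with the Srsf2 mutation. Genes of late neutrophils, suppressor cells, red cells and the interferon response were higher in the double mutant libraries, and B lymphoid genes were lower. Mmp8 (ENSMUSG00000005800, chromosome 9, 7558456 to 7568485) went from 158.6 ± 3.95 to 765.6 ± 5.51 CPM, 4.83-fold higher (log2 fold change 2.27 ± 0.0641 SE, adjusted p = 8.15e-13 by the edgeR quasi-likelihood test). Rhag rose 8.09-fold (3.02 ± 0.0826, adjusted p = 5.85e-13), and Rsad2 (ENSMUSG00000020641, chromosome 12, 26442746 to 26456452) rose 6.69-fold (2.74 ± 0.0679, adjusted p = 3.34e-13). Dntt (ENSMUSG00000025014, chromosome 19, 41029275 to 41059525), the polymerase that adds bases at antigen receptor joints, fell from 200.9 ± 24.5 to 31.76 ± 1.09 CPM (-2.66 ± 0.0864, adjusted p = 2.13e-12).

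All 23 late neutrophil genes rose (23 adjusted over the list alone; median 1.11, adjusted p = 5.57e-30), among them Retnlg, a resistin-like gene, 7.92-fold, and the chemokine receptor gene Cxcr2 4.54-fold. S100a8 went from 2544 ± 462 to 5678 ± 141 CPM (1.16 ± 0.106, adjusted p = 3.28e-07), and S100a9 rose by 1.18 ± 0.111. Of 31 suppressor cell genes, 22 rose and 2 fell (the same adjusted over the list alone; median 0.71, adjusted p = 3.52e-17). Il1b rose 4.3-fold, the lectin gene Clec4d 6.6-fold, and Csf3r, the receptor of granulocyte colony-stimulating factor, 2.47-fold. Arg1 (0.42 ± 0.479, adjusted p = 0.55) and Nos2 (0.96 ± 0.598, adjusted p = 0.247) stayed under 2 CPM in each library of both groups, where the difference was not detectable at this depth. Early neutrophil genes were not called (4 of 18 higher, 10 lower, the same adjusted over the list alone; adjusted p = 0.23), and Mpo fell by 0.46 (SE 0.0604, adjusted p = 1.95e-05).

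Of 30 erythroid genes, 29 rose and 0 fell (30 and 0 adjusted over the list alone; median 2.23, adjusted p = 1.55e-134). Epb42, a protein of the red cell membrane skeleton, rose 6.64-fold, and Slc25a37, a mitochondrial iron carrier, 3.98-fold. Globin transcripts made up 1.73%, 1.76% and 1.61% of counts in the double mutant libraries. Of 41 interferon-stimulated genes, 33 rose and 2 fell (35 and 3 adjusted over the list alone; median 0.82, adjusted p = 1.82e-25), with Oas3, which senses double-stranded RNA, 4.9-fold higher. Of 23 B lymphoid genes, 19 fell and 2 rose (the same adjusted over the list alone; median -1.54, adjusted p = 1.97e-32), with Vpreb1, part of the surrogate light chain, 6.47-fold lower. Mast cell and basophil genes were called lower (5 of 18 higher, 10 lower; 5 and 11 adjusted over the list alone; median -0.60, adjusted p = 1.24e-06), with Cyp11a1 2.53-fold lower and Il6 2.68-fold lower.

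Monocyte and macrophage genes were called higher (17 of 28 higher, 3 lower; adjusted p = 0.0565 with an estimated correlation), with Fn1, the gene of fibronectin, 6.87-fold higher. Mitosis genes were called higher (16 of 32 higher, 1 lower; adjusted p = 0.172 with an estimated correlation), and Mki67 went from 878.2 ± 166 to 1430 ± 33.1 CPM (0.70 ± 0.1, adjusted p = 4.28e-05). DNA replication genes were called lower (6 of 43 higher, 20 lower; adjusted p = 0.356 with an estimated correlation), with the helicase gene Mcm3 at -0.46 ± 0.0557. Eosinophil genes (8 of 10 higher, 0 lower) and Toll-like receptor and interleukin-1 genes (12 of 35 higher, 3 lower) were called higher, each with adjusted p = 0.414 with an estimated correlation. The Toll-like receptor call was lost without genes on X and Y (adjusted p = 0.125). NF-kB and TNF targets (11 of 33 higher, 8 lower, adjusted p = 0.758) and immediate early genes (9 of 29 higher, 5 lower, adjusted p = 0.906) were not called, and neither were T and NK genes (9 of 24 higher, 0 lower, adjusted p = 0.202). Counts in this paragraph were the same adjusted over the list alone except for monocytes (17 and 4), mitosis (17 and 1), DNA replication (6 and 22), Toll-like receptors (13 and 3) and immediate early genes (9 and 7).

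The genes with the largest folds included Asprv1, a protease gene, from 5.085 ± 0.834 to 67.34 ± 1.68 CPM, and Il1f9, a cytokine of the interleukin-1 family, from 10.01 ± 1.59 to 126.1 ± 1.24 CPM. Scn4b, a sodium channel subunit gene, fell from 18.69 ± 0.884 to 0.7938 ± 0.3 CPM. Rpl29 was also lower here, at 275.4 ± 7.58 against 588.1 ± 82.5 CPM (-1.09 ± 0.107). In all 6511 genes changed, 3436 higher and 3075 lower (1378 and 541 at a change of at least 2-fold). With upper-quartile scaling the balance turned, to 3075 higher and 3846 lower. Of the lists 11 were called, and 6 of them with an estimated correlation as well: erythroid, late neutrophil, suppressor cell, interferon, B lymphoid and mast cell. Camera adjusted p with that correlation was 0.0289 for late neutrophil, 0.000957 for suppressor cell and 2.43e-05 for erythroid genes.

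**Figure D3:**
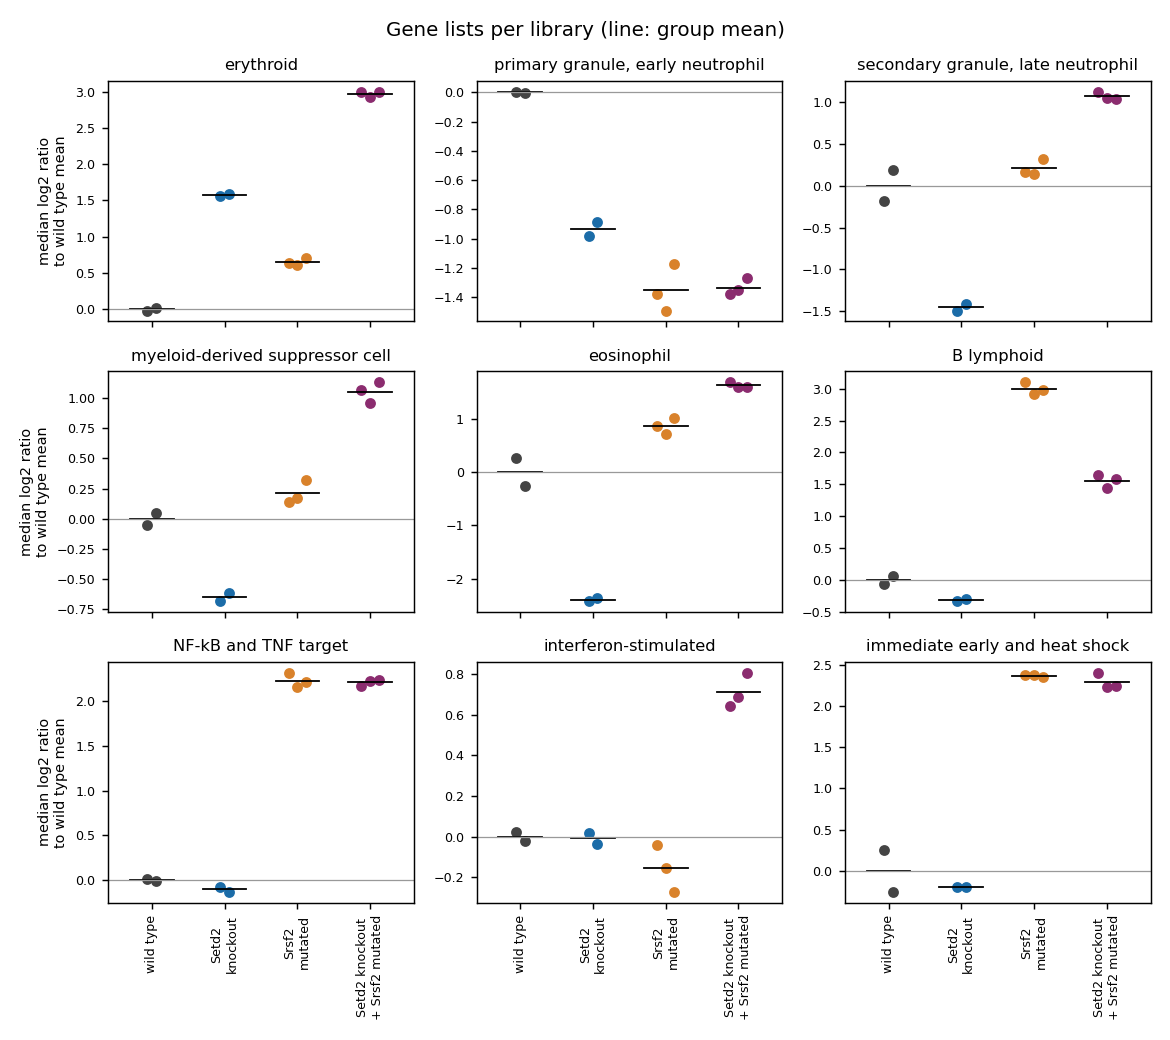
Median log2 ratio to the wild type mean over the members of 9 gene lists, per library (each point is a library, lines are group means). The late neutrophil list is lowest in Setd2 knockout and highest in double mutant libraries, and the erythroid list is highest in double mutant libraries.

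The interaction asks whether the loss of Setd2 acted differently with and without the Srsf2 mutation, over all 10 libraries. Late neutrophil and suppressor cell genes fell with the labelled loss of Setd2 in the wild type background and rose with it in the Srsf2 mutated background. Counts of Setd2 itself also moved in opposite directions, by 0.55 and -0.60 on the log2 scale, and do not check the genotype. S100a8 differed by 2.90 ± 0.17 (SE) on the log2 scale between the backgrounds, and Il1r2, a decoy receptor of interleukin-1, by 4.12 ± 0.112, from 13.25 to 4.693 CPM in one background and from 32.02 to 197.1 CPM in the other. Of 23 late neutrophil genes, 21 responded more positively in the mutated background and 0 less (22 and 0 adjusted over the list alone; median difference 2.61, adjusted p = 3.34e-64). Of 31 suppressor cell genes this held for 22 and 0 (23 and 0 adjusted over the list alone; 1.60, adjusted p = 1e-30), and of 10 eosinophil genes for 10 and 0 (the same adjusted over the list alone; 2.68, adjusted p = 9.15e-26).

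Interferon-stimulated genes also differed (29 of 41 more positive, 4 less, the same adjusted over the list alone; median 0.81, adjusted p = 2.05e-14), including Oas3 at 2.80. Erythroid genes rose in both backgrounds, by slightly more in the mutated one (16 of 30 more positive, 1 less; 17 and 1 adjusted over the list alone; median 0.47, adjusted p = 3.51e-05). B lymphoid genes (2 of 23 more positive, 17 less, the same adjusted over the list alone; median -1.24, adjusted p = 7.37e-12), mast cell genes (2 of 18 and 12; 4 and 12 adjusted over the list alone; -1.15, adjusted p = 1.01e-05) and splicing factors (3 of 46 and 21; 3 and 22 adjusted over the list alone; -0.24, adjusted p = 3.51e-05) differed the other way. Clk4 and the RNA-binding protein gene Hnrnph1 differed by -1.27 and -1.75. Both were low in the wild type libraries alone, Clk4 at 30.51 and 34.02 CPM against 86.16 to 122.4 CPM in all others. Their differences thus rest largely on the wild type libraries. Splicing factors were called higher in both comparisons with wild type, which share those libraries. Early neutrophil genes differed with the preset correlation (17 of 18 more positive, 0 less; 18 and 0 adjusted over the list alone; adjusted p = 0.109 with an estimated correlation), as did mitosis genes (19 of 32, 1 less; 22 and 2 adjusted over the list alone; adjusted p = 0.0673). The interaction of Mki67 was 0.51 (adjusted p = 0.0205) and ended with upper-quartile scaling (0.37, adjusted p = 0.0871), with the stricter filter (0.0573), and without wild type replicate 2 (0.0512), Setd2 knockout replicate 1 (0.0604) or Setd2 knockout replicate 2 (0.113).

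In all 6160 genes differed, 3229 more positive and 2931 less in the mutated background. With upper-quartile scaling these were 2438 and 4039, with the median of all genes at -0.211 in place of -0.0652, so list medians are to be read against a shift of that size. Of the lists 17 were called, and 9 of them with an estimated correlation as well: the 8 given with full values above (late neutrophil, suppressor cell, eosinophil, interferon, erythroid, B lymphoid, mast cell and splicing factor) and the sex-linked list, in which Xist differed by 11.72. Camera adjusted p with that correlation was 0.0084 for late neutrophil, 0.000403 for suppressor cell and 0.0374 for erythroid genes. Across the 19289 genes the log2 fold changes of the loss of Setd2 in the 2 backgrounds, which share no library, correlated at r = 0.167 (Spearman rho = 0.167), with genes not being independent replicates. Genes higher in both numbered 921 against 641.8 if the calls were independent, and genes lower in both 1102 against 613.1. Genes lower in Setd2 knockout and higher in double mutant numbered 952 against 685.1, and the reverse 377 against 574.4.

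**Figure D4:**
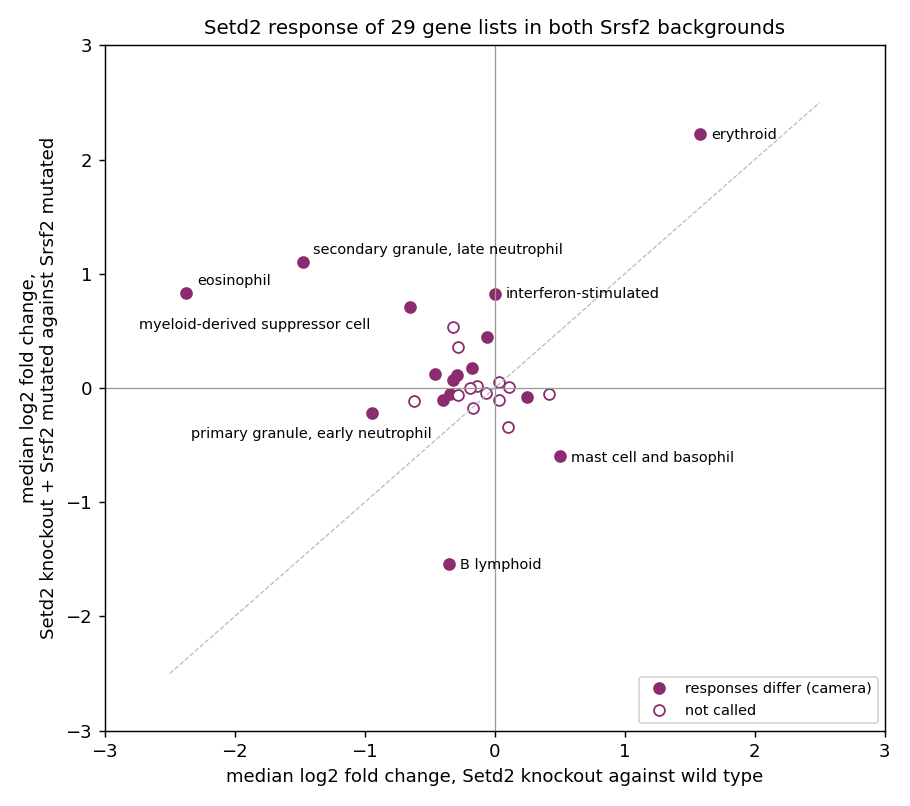
Median log2 fold change of 29 gene lists for Setd2 knockout against wild type (horizontal axis) and double mutant against Srsf2 mutated (vertical axis); filled points are lists whose responses differed by camera, and the dashed line marks equal responses. The late neutrophil list lies at -1.48 and 1.11, and the erythroid list is above 0 on both axes.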

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

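The tests of neighbouring DNA, of Rpl29 copies, of dilution by red cell precursors, of mature neutrophil markers, of handling and of macrophages were chosen only after the results were seen. Leaving out each library was set earlier. The late neutrophil and suppressor cell genes and the lists and genes in the last 2 paragraphs stand out because the response to the loss of Setd2 differed between the 2 Srsf2 backgrounds by the edgeR or camera test of the difference itself, which held for 6160 genes. The chromosome 9 and NF-kB patterns were taken up for other reasons. Groups of 2 or 3 libraries were not tested for outlying ones, though Srsf2 mutated replicate 3 stood apart on the second principal component (75.5 against 36.9 and 42.5).

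Late neutrophil genes fell with the labelled loss of Setd2 in the wild type background and rose in the Srsf2 mutated one, with a median difference of 2.61 on the log2 scale, and suppressor cell genes did so with 1.60. Both lists moved the same way, so a change particular to suppressor cells cannot be told apart from one of neutrophils. Setd2 itself differed by 0.55 in the first background and by -0.60 in the other, and a link to these genes was not tested. A larger share of red cell precursors would lower the genes of all other cell types, but the late neutrophil median rose by 1.11 in double mutant against Srsf2 mutated libraries while the erythroid median rose by 2.23, so dilution is argued against there. In Setd2 knockout against wild type the medians were -1.48 for late neutrophil and -0.46 for megakaryocyte genes. They were 0.11 for stem cell and 0.50 for mast cell and basophil genes. Equal dilution of all other types as the only cause is argued against there too, while a smaller part stays open. No single library made the difference, since the lowest late neutrophil median difference on leaving out a library was 2.35, without wild type replicate 2. More late neutrophils in the double mutant libraries may account for the rise: of 12 mature neutrophil markers in none of the other lists 12 rose (100%, exact Clopper-Pearson 95% interval 73.5% to 100%), such as Mxd1 from 205.7 to 548.7 CPM and Gda from 180.4 to 419.8 CPM, replacing a first test on 18 genes of the late neutrophil list itself, whose members define the pattern. The interval takes the markers as independent, which genes of the same cell type need not be. In Setd2 knockout against wild type, 0 of the same 12 markers rose and 8 fell (median -0.883). Fewer late neutrophils may therefore account for the fall there. These markers cannot tell more or fewer cells from a changed expression per cell. A c-Kit-positive, lineage-negative sort, stated for the single-cell samples, should remove mature neutrophils, wild type libraries hold Gda at 274.7 CPM too, and a higher expression per cell with the loss of Setd2 in Srsf2 mutated cells stays open and untested in bulk libraries.

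Large changes lay near Setd2 on chromosome 9: of 383 tested genes within 20 Mb, 18 changed at least 2-fold the same way in both Setd2 comparisons (4.7%), against 410 of 18884 elsewhere (2.17%; odds ratio 2.22, 95% interval 1.29 to 3.61, Fisher's exact p = 0.00243 for the higher side, against 0.0058 within 10 Mb and 0.0438, with an odds ratio of 1.6, within 40 Mb, and with neighbouring genes not being independent). The Rpl29 reads lost in Setd2 knockout libraries, 595.7 CPM over raw totals without TMM scaling, were not matched by counts at its copies. The 99 copies found by sequence gained 28.1 CPM net (42.1 CPM counting gains alone) in the same unit. Single copies moved: Gm8210 went from 0.287 to 17.2 CPM and Gm10709 from 11.9 to 0.185 CPM in Setd2 knockout against wild type. Gm8210 also went from 0.528 to 15.2 CPM in double mutant against Srsf2 mutated libraries. The assignment of shared reads is not stated, so the sum cannot show whether such reads were left uncounted. A first test on any pseudogene, with 110 CPM at Gm8995, was dropped because that gene is no copy. DNA of another strain carried along with the Setd2 allele could change its neighbours, and 5.14% of tested genes, or 4.69% of those on other chromosomes, have surroundings with as large a share of such changes, on either side of a bound of 5%, with a window chosen after chromosome 9 had been looked at. This cannot be told apart from uneven spacing of changed genes, as the strains are not given in the sources used here. A response of these genes to the loss of Setd2 itself stays open as well, untested.

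NF-kB target genes and immediate early and heat shock genes were higher in Srsf2 mutated than in wild type libraries, by medians of 2.26 and 2.22. Handling of the cells before lysis could raise early response genes, whose median over 8 of them, all members of the immediate early list, was 1.48 with an SE of 0.847: Fosb (4.30) and Atf3 (4.49) rose, Dusp1 (-0.42) fell, and Fos stood at 612.5 and 611.2 CPM. Since these 8 genes are part of the pattern, their median cannot decide for or against handling. Macrophages could bring such genes along, but 11 resident macrophage markers, 9 of them also in the monocyte and macrophage list, had a median of 0.448 with an SE of 0.354, C1qa rising from 8.738 to 19.52 CPM and Vcam1 falling from 120.8 to 35.89 CPM. Each test had a bound for a rise and a lower bound for no rise. The handling value lies within an SE of the bound for a rise, and the macrophage value within an SE of the bound for no rise. Earlier forms of these tests ignored the SE and would have favoured handling and argued against macrophages, and they were changed after the values were seen. Handling and macrophages among the cells stay open, although a lineage-negative sort, stated for the single-cell samples, should remove macrophages, and so does the Srsf2 mutation itself, untested apart from the sex-linked state that differs between the same groups.

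Eosinophil genes differed between backgrounds by a median of 2.68, and interferon-stimulated genes by 0.81. Erythroid genes differed by 0.47, B lymphoid genes by -1.24, mast cell and basophil genes by -1.15, and splicing factor genes by -0.24. The sex-linked list differed by a median of 0.15. These 7 lists were also called with an estimated correlation. The others were not, with adjusted p = 0.109 for early neutrophil (median 0.63), 0.149 for Toll-like receptor and interleukin-1 signaling (0.48) and 0.149 for cytokine receptor and JAK-STAT genes (0.27). For megakaryocyte (0.51) the value was 0.167, for monocyte and macrophage (0.52) 0.0572, for mitosis (0.35) 0.0673, for ribosomal protein (0.29) 0.768 and for oxidative phosphorylation genes (0.27) 0.769. The oxidative phosphorylation call also ended without wild type replicate 2 (adjusted p = 0.0514), Setd2 knockout replicate 1 (0.0694) or Srsf2 mutated replicate 2 (0.073).

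Among single genes, the difference was 11.72 for Xist, 4.12 for Il1r2, 2.90 for Mmp8, 2.63 for Trem1 and 3.37 for Cxcr2. It was -2.93 for Fam129c, -3.01 for Mir17hg, the host of a microRNA cluster, -2.66 for the nuclear RNA Neat1, -1.75 for Hnrnph1 and -1.58 for Arglu1. Of these, Mir17hg, Neat1, Hnrnph1 and Arglu1 were low in the wild type libraries alone. Neat1 stood at 9.668 and 12.61 CPM there and at 103.3 to 172.6 CPM in all others. Hnrnph1 stood at 291.7 and 303.7 CPM against 736.5 to 990.8 CPM. The differences of these genes thus rest largely on the wild type libraries, whose sex-linked state differs from that of all others. Xist went from 485.5 CPM in wild type to 0.5982 CPM in Setd2 knockout libraries, and from 1.783 CPM in Srsf2 mutated to 7.405 CPM in double mutant libraries. The sex-linked state differs between wild type and Setd2 knockout libraries, so the Xist difference cannot be read as a response to the loss of Setd2.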

How the results depend on the processing

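A minimum change of 2-fold and the removal of genes on X and Y were chosen only after the results were seen; the other settings were set earlier, and those meant for tables without counts were not run. With an estimated correlation, the lists called were 7 for Setd2 knockout against wild type, 8 for Srsf2 mutated against wild type, 6 for double mutant against Srsf2 mutated and 9 for the interaction, since correlation between genes widens the test. Without a filter on low counts, 17 lists were called for double mutant against Srsf2 mutated in place of 11, and the cause was not tested. At a change of at least 2-fold, 2526, 4799, 1919 and 2702 genes were called in the 4 comparisons. Leaving out each library in turn gave 4792 to 5926 genes for Setd2 knockout against wild type, lowest without Setd2 knockout replicate 1, where the lone library left is assumed to vary like those of the other groups. The correlation of the Setd2 effects between backgrounds then ranged from 0.118 (without Setd2 knockout replicate 1) to 0.224 (without Srsf2 mutated replicate 2), and the cause was not tested. The other gene counts stayed within 1.5 times their value under each setting run. Outside these settings, the deposited comparison of double mutant against Srsf2 mutated holds 1476 genes at the same threshold, against 6511 here. That fit appears to have included libraries that were not used here.

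Of the lists called with all libraries, 0 changed direction under the settings run. Among the others, immediate early and heat shock genes were called higher without wild type replicate 1 and lower without replicate 2 in Setd2 knockout against wild type (adjusted p = 0.0281 and 0.000168), and the other way round in the interaction (0.0179 and 0.0192). The stricter filter, which tests fewer genes (11260), ended 4 of the list calls in each of Setd2 knockout against wild type, Srsf2 mutated against wild type and the interaction, and 3 in double mutant against Srsf2 mutated. Over 5821 checks of named genes, 5765 gave the same call, 48 no longer passed the threshold, 8 newly passed it and 0 reversed. The most calls, 11, ended without wild type replicate 2. Removing genes on X and Y changed no named gene's call (398 of 398 the same). The counts of all other genes stay as they are, so this cannot show whether the sex-linked state changed them. A replicate block gave 7513, 10501, 6642 and 6188 genes, and the residuals of libraries with the same replicate number in different groups correlated at -0.0278 to 0.0398 over 13 pairs, none above 0.1, so the numbers do not pair the libraries. The 6 libraries of double mutant and Srsf2 mutated allow 10 splits into groups of 3, which is too few for a share under 0.05; the real split gave 6511 genes by edgeR, 1 of the 10 gave as many, and the highest of the other splits gave 0 (718 against 8142 at an unadjusted p under 0.05).

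Depth limits genes near the floor, such as Nos2, and counts of near-identical genes (globins, Ear genes, immunoglobulins, ribosomal protein copies) depend on how shared reads were assigned, which is not stated. Across genes, fold change correlated with gene length at Spearman -0.0763, -0.221, -0.029 and 0.0734 in the 4 comparisons.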

Other observations

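The test of plasma cell markers was chosen only after the results were seen. Further genes named by the same rule as in the report also changed. Pkhd1l1, a large membrane protein gene, rose 24-fold in Setd2 knockout against wild type and 11.4-fold in double mutant against Srsf2 mutated libraries by the edgeR test. Epor, the erythropoietin receptor gene, also rose in double mutant against Srsf2 mutated libraries, 4.79-fold. Malat1, a long nuclear RNA, went from 64.93 ± 18.3 CPM (SD, n = 2) in wild type to 754.4 ± 4.64 in Setd2 knockout libraries (n = 2). It stood at 543.3 to 1042 CPM in the Srsf2 mutated and double mutant libraries, so the wild type libraries alone were low. Chit1, a chitinase gene of myeloid cells, fell from 12.94 ± 1.99 to 1.026 ± 0.0151 CPM in the same comparison. It stood at 0.4136 to 1.028 CPM in the Srsf2 mutated and double mutant libraries, so the wild type libraries alone were high. Among chromatin enzymes, Tet2, which oxidises methylated cytosine, rose 2.52-fold in Setd2 knockout against wild type, and Kdm6b, a histone demethylase, rose 4.81-fold in Srsf2 mutated against wild type. Tet2 stood at 26.55 and 28.86 CPM in the wild type libraries and at 55.03 to 93.36 CPM in all others. Thbs1, the gene of thrombospondin, rose 32.2-fold in Srsf2 mutated against wild type. Klf4, a transcription factor of monocytes, rose 5.19-fold there.

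Immunoglobulin genes, chosen after their values were seen, were high in libraries with the Srsf2 mutation. Igha stood at 370.0 CPM in wild type, 348.3 in Setd2 knockout, 3118 in Srsf2 mutated and 6388 in double mutant libraries, and Jchain, which joins antibody chains, at 65.11, 63.66, 525.7 and 1108 CPM. Not all followed: Ighg1 fell from 33.46 to 4.013 CPM and Ighd from 8.694 to 5.303 CPM in double mutant against Srsf2 mutated libraries. A hypothesis is that plasma cells in these libraries may carry them. Of 9 tested plasma cell markers other than immunoglobulin genes and Jchain, 5 rose in Srsf2 mutated against wild type (55.6%, exact Clopper-Pearson 95% interval 21.2% to 86.3%) and 2 in double mutant against Srsf2 mutated (22.2%, 2.81% to 60%), so both intervals include 50% and plasma cells stay open. The first form of the test also counted 4 immunoglobulin genes and Jchain, which belong to what it was to explain, with 10 of 14 and 6 of 14 rising. It ignored the interval and would have argued against plasma cells, and both points were changed after the values were seen. Mzb1, a plasma cell chaperone, had few counts, at 0.3524 and 0.2645 CPM in the Srsf2 mutated and double mutant libraries. The markers Prdm1 (0.7645, 6.421 and 10.53 CPM) and Derl3 (2.411, 5.735 and 10.59 CPM) rose from wild type to Srsf2 mutated to double mutant libraries. Irf4 rose to 111.4 CPM and then fell to 70.7. Of 9 markers under 10 CPM in wild type, immunoglobulin genes included, 8 rose in Srsf2 mutated against wild type. In double mutant against Srsf2 mutated 4 of these 9 rose. A lineage-negative sort, stated for the single-cell samples, should remove plasma cells.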
